A study of Homo sapiens with 4 samples.

How the data were processed

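RNA was measured by sequencing in 4 libraries of the human breast cancer cell line MCF-7: 2 libraries of the parental cells and 2 libraries of cells in which the cadherin gene FAT1 had been targeted by CRISPR, labelled FAT1 CR. Per the labels' protocols, both kinds of cells were grown in the same medium with serum, total RNA was extracted on columns, and libraries were made with a kit (NEBNext Ultra RNA). The labels do not say whether the strand of the RNA was kept. The protocols name a single FAT1 CR derivative. The group of each library was taken from its cell type label and its replicate number from its title. The labels do not say that the 2 replicates of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

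The deposited files hold whole-number counts per exonic bin, not normalized, with the layout of the featureCounts program, per the file headers. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, featureCounts from Subread 1.5.2 and DESeq2, without the order or the settings of the steps. The notes name the genome build hg19, whereas the positions in the files are those of GRCh38: of 52373 genes that the files share with GENCODE 29, 96.5% had the same start and end in both. Positions are therefore given on GRCh38, as in the files. Each file lists the same 597973 bins, which cut the exons of 54848 entries into pieces that do not overlap within a strand. Of these entries, 2031 are joint entries for overlapping genes on 1 strand, together 5228 genes, and they held 19.1% of the counts. A joint entry was named after 1 gene where at least 90% of its counts lay in that gene's GENCODE 29 exons, which was so for 1199 of them. Names were looked up by Ensembl identifier in the gene name table of the reference.

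Bins of a single base between touching bins held counts in 69.2% of 6101 cases, so a read was counted in every bin it overlapped. A gene's value, the sum over its bins, therefore counts overlaps of reads with bins and exceeds its number of reads. Totals per library were 66949102 and 68175867 bin counts for parental replicates 1 and 2, and 63598417 and 54547256 for FAT1 CR replicates 1 and 2. The number of reads behind them is not given in the sources used here. Since 1 read adds several counts, counting intervals and floors are narrower than read numbers would allow, and they cover counting error only. Because the strand setting is not known, a gene and an antisense partner on the same bases may share counts. This concerns at least 23251 bins, those that overlap a bin starting before them, and their partners. Values of near-identical copies such as histone, HLA and ribosomal protein genes with pseudogenes are also uncertain.

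Gene sums were analysed with edgeR 4.0.16 in R 4.3.3. Genes passed the filterByExpr function at its defaults (minimum count 10, minimum total count 15), library sizes were scaled by TMM, and the 2 groups were compared by the quasi-likelihood F test with no covariate. P-values were adjusted by the Benjamini-Hochberg method, a gene was called changed at an adjusted p under 0.05, and counts are also given for an absolute log2 fold change of at least 1. The log2 fold change is FAT1 CR over parental, fitted with a prior count, and its standard error (SE) was taken as its size divided by the square root of F. Levels are CPM from the cpm function of edgeR, with TMM-scaled library sizes, with the SD over 2 libraries. Where a group had 0 counts, a fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with an exact (Clopper-Pearson) 95% interval.

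Gene lists (30, besides the key genes) were fixed before the data were examined. The 26 with at least 5 tested members were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 26, and again with an estimated correlation. With 2 libraries per group the estimated form has few degrees of freedom, so a missing call there does not decide against a list. The neighbourhood of FAT1 was the tested genes within 5 Mb on either side, set beside 10000 random sets matched on mean expression and, after the data were seen, beside blocks of as many neighbouring genes elsewhere. Chromosome shifts were described by the median log2 fold change of each chromosome and of windows of 50 neighbouring tested genes, with no replicate test for windows.

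The genes named in the text were chosen by a rule fixed before the data were examined. The rule took FAT1 and a list of key genes whatever their result. It took the 10 largest rises and the 10 largest falls in log2 fold change among changed genes with a mean of at least 5 CPM, non-overlapping groups and a gene symbol. It also took the 5 largest rises and falls in mean CPM among genes changed by at least 1 on the log2 scale, and up to 4 changed members of each list with the largest absolute log2 fold change. Other genes are said to have been chosen after their values were seen.

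Alternatives tried were other scalings (the RLE factors of DESeq2, upper quartile, library size only), no low-count filter and a stricter filter (at least 1 CPM in at least 2 libraries), the DESeq2 1.42.0 Wald test, limma-voom, leaving out each library, a replicate block, a fold threshold in the test, adjusted p under 0.01, other list tests, and windows of 2 and 10 Mb around FAT1. After the files had been seen, 3 more were added: the highest bin of each gene, bins of at least 200 bases, and leaving out joint entries. On simulated counts with 200 of 17705 genes changed in a comparison of FAT1 CR with parental, the test recovered 70% of genes changed by a log2 fold of 1 and 90% of those changed by 2, with 12 false calls (6.98% of calls). In simulated data with a log2 rise of 0.5 in the Hippo list, that list was called and 0 of 24 other lists were. Genes were simulated independently of each other, so this does not show how often lists are falsely called when their members move together. Genes outside the raised list were simulated without a change, whereas 48.3% of tested genes were called in the real comparison. The simulation therefore does not show how readily a real list with such a rise would be called. A test of the ratio of counts in the 5′ and 3′ parts of each gene (limma) recovered 99.5% of 200 simulated changes of 2 on the log2 scale among 11050 genes, with 6 false calls. Use of single exons was not tested.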

Results

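RNA levels were compared between the parental MCF-7 line, an estrogen receptor-positive breast cancer line, and a derivative in which FAT1, a large cadherin of the cell surface, had been targeted with CRISPR (FAT1 CR). The series asks how RNA expression differs after FAT1 loss, and its title names the Hippo pathway and resistance to CDK4/6 inhibitors. There were 2 libraries per group, with bin counts of 66949102 and 68175867 for parental replicates 1 and 2 and 63598417 and 54547256 for FAT1 CR replicates 1 and 2. A count was found for 31365 genes in at least 1 library, and 18054 genes passed the filter and were tested. Across genes, log2 CPM correlated with r = 0.992 between the parental libraries, 0.994 between the FAT1 CR libraries and 0.943 to 0.944 between groups. Genes are not independent replicates, so these values describe similarity only. In a chi-square comparison of counts in the highest bin of each gene, the statistic per degree of freedom was 10.3 within the parental pair and 1.68 within the FAT1 CR pair, so neither pair held duplicate counts, although the FAT1 CR libraries were closer to each other. The other pairs gave 49.8 to 56.1.

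FAT1 (ENSG00000083857, chromosome 4, 186587783 to 186726722, minus strand) was nearly absent from the FAT1 CR libraries. Its level was 27.1 ± 7.8 CPM in parental cells and 0.73 ± 0.16 CPM in FAT1 CR cells (SD, n = 2 each), a log2 fold change of -5.20 (SE 0.26, edgeR quasi-likelihood test, adjusted p = 1.4e-06). The counts were 2130 and 1477 in the parental libraries and 54 and 34 in the FAT1 CR libraries. Of its 59 exonic bins, 42 had at least 10 counts in both parental libraries, and in all 42 both FAT1 CR libraries lay below both parental libraries.

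**Figure D1:**
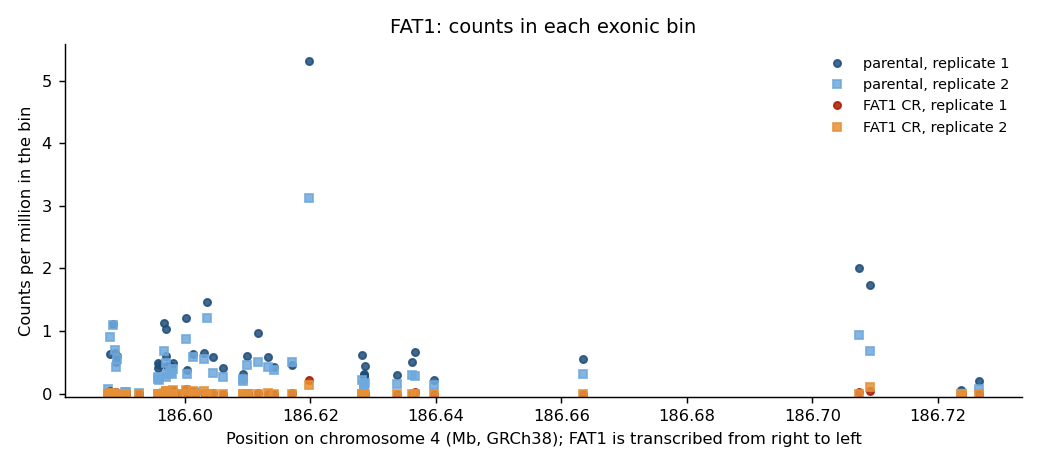
CPM in each exonic bin of FAT1 (y axis) by its position on chromosome 4 in Mb (x axis), with a point per library. FAT1 CR libraries (red and orange) lay near 0 along the gene and below the parental libraries (blue) in all 42 bins with at least 10 counts in both parental libraries.

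Genes beside FAT1 were also lower in FAT1 CR cells. The 29 tested genes within 5 Mb of FAT1 lay at 181874438 to 189963204 on chromosome 4. Only ENSG00000278974 and FRG1 lay at higher positions than FAT1. Of the 29 genes, 22 were lower, 0 were higher and 7 did not pass the edgeR test. Their median log2 fold change was -0.96, against -0.01 for all tested genes, and 0 of 10000 random sets of scattered genes matched on expression had a median as low (95% of the sets lay between -0.26 and 0.30). Of 17336 blocks of 29 neighbouring genes elsewhere, 41 had a median as low, in 4 separate regions on chromosomes 6, 12 and 16. WWC2, which encodes a relative of the Hippo regulator WWC1, fell from 29.02 ± 0.76 to 7.33 ± 0.24 CPM (log2 fold change -1.98, SE 0.09, adjusted p = 1.2e-06). Among neighbours chosen after their values were seen, TENM3, a teneurin of the cell surface, fell from 21.2 ± 5.9 to 1.20 ± 0.39 CPM, and CASP3, an executioner caspase, from 9.93 ± 0.63 to 4.56 ± 0.24 CPM (adjusted p = 5.2e-06 and 0.00015). TENM3-AS1 had 334 counts in the parental libraries and 0 in the FAT1 CR libraries, which is at least 99.2-fold lower. ACSL1 did not pass, at 16.1 ± 1.2 and 17.0 ± 0.47 CPM (adjusted p = 0.56).

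FAT1 CR cells differed from parental cells in 8726 genes (48.3% of those tested), of which 4303 were higher and 4423 lower. Which direction held more genes depended on the scaling, with 4831 higher and 3937 lower by upper quartile factors and 4583 and 4171 by library size only. At an absolute log2 fold change of at least 1, there were 1761 higher and 1343 lower genes. The libraries of the groups did not overlap for 74.6% of tested genes, where chance gives 33.3%. The largest rises in log2 fold change were in MUC5AC (a gel-forming mucin), KLK11 (a secreted serine protease), SLFN11, HMCN1, RUBCNL, HEY2, RGS22, FIGN, LOXL1 and S100P. KLK11 rose from 0.46 ± 0.05 to 134 ± 1.1 CPM and HMCN1, which encodes a large extracellular matrix protein, from 1.00 ± 0.14 to 154 ± 1.6 CPM (log2 fold changes 8.19 and 7.26, SE 0.11 and 0.10). RUBCNL shares its entry with the pseudogene PPP1R2P4. The largest falls were in TDRD1, IL20, IFI44, ADAMTS1, COL2A1, FOXP2, ARHGEF6, XAF1, DDX60L and IFIT1. TDRD1, a gene of the germline, had 2721 counts in the parental libraries and 0 in the FAT1 CR libraries, which is at least 809-fold lower. IL20 had 1366 counts against 1, a ratio of 1220 (95% interval 218 to 48100), and ADAMTS1, a secreted protease, had 1360 against 2, a ratio of 606 (167 to 5010). COL2A1, the main collagen of cartilage, fell from 42.8 ± 0.29 to 0.31 ± 0.21 CPM. With few counts in 1 group, log2 fold changes moved between alternatives. That of MUC5AC (9.29) was 10.23 and 8.69 without parental replicates 1 and 2 and 8.07 with the highest bin. That of COL2A1 (-7.06) was -8.04 without FAT1 CR replicate 1 and -5.55 with bins of at least 200 bases, and that of ARHGEF6 (-6.44) was -5.95 and -7.13 without FAT1 CR replicates 1 and 2. Without the same libraries in turn it was -9.01 and -12.39 for IL20 (-9.94 with both) and -12.33 and -8.27 for ADAMTS1 (-9.09 with both). The intervals cover counting error only and were not built to allow for such differences between libraries.

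By mean level, the largest rises among genes changed by at least 1 on the log2 scale were in the glycolytic enzyme genes ALDOA (2719 ± 182 to 6063 ± 32.4 CPM) and GAPDH (1878 ± 118 to 3916 ± 54.4 CPM), SPTSSB, TFF1 and UGDH. The largest falls were in ATP5F1B, a subunit of the mitochondrial ATP synthase (2941 ± 126 to 1377 ± 56.8 CPM), the amino acid transporter genes SLC38A1 and SLC38A2, CD63 and the estrogen receptor coactivator gene NCOA3. SLC38A1 fell from 2052 ± 181 to 450.5 ± 13.5 CPM (adjusted p = 1.5e-07). Fewer genes were called without either FAT1 CR library, and more without either parental library. In such fits the lone library is assumed to vary like the pair of the other group. The parental pair differed more than the FAT1 CR pair (chi-square per degree of freedom 10.3 and 1.68). Calls lost or gained on leaving out a library, here and for single genes below, therefore reflect that spread as well as the library left out.

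Of the D-type cyclin and CDK genes that CDK4/6 inhibitors address, CDK6 showed the largest change. CDK6 rose from 2.18 ± 0.17 to 16.4 ± 1.6 CPM (log2 fold change 2.91, SE 0.14, adjusted p = 1.2e-06). CDK4 fell from 559 ± 38 to 381 ± 6.0 CPM (-0.55, SE 0.06), and CCND1, the cyclin D1 gene, rose from 355 ± 14 to 487 ± 0.85 CPM (0.46, SE 0.06). CDK4 lies in a window of 50 genes on chromosome 12 with a median of -0.86, where 36 genes were lower and 1 higher. Its fall was thus smaller than the median of its window. RB1, the tumor suppressor that these kinases phosphorylate, did not pass, at 75.7 ± 0.78 and 77.5 ± 0.62 CPM (adjusted p = 0.69). Of 20 tested genes of the cyclin D-CDK4/6-RB list, 8 were higher, 6 lower and 6 not called (9 and 6 adjusted over the list alone). CDK inhibitor genes went both ways: CDKN2C (8.45 ± 1.6 to 18.1 ± 0.98 CPM) and CDKN2D rose, each by 1.10 on the log2 scale, and CDKN1A, which encodes p21, fell from 106 ± 10 to 50.6 ± 2.4 CPM. The list as a whole was not called (camera, adjusted p = 0.54, median 0.20).

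Genes of the Hippo pathway, which restrains the coactivators YAP and TAZ, changed in both directions. Among 26 tested components, 12 were higher, 9 lower and 5 not called, with the same numbers adjusted over the list alone (camera, adjusted p = 0.61, median 0.06). The kinase gene LATS2 rose from 8.71 ± 0.20 to 18.5 ± 0.17 CPM and AMOTL1, an angiomotin relative, from 10.6 ± 0.67 to 20.9 ± 0.48 CPM. TEAD3, a partner of YAP on DNA, fell from 24.6 ± 1.4 to 12.6 ± 0.20 CPM, and WWC2 was the other member with a log2 fold change below -0.9. YAP1 (41.6 ± 1.4 and 43.4 ± 1.6 CPM) and the TAZ gene WWTR1 (18.6 ± 0.77 and 17.1 ± 0.02 CPM) did not pass (adjusted p = 0.54 and 0.30), although WWTR1 was called lower from the highest bin of each gene (adjusted p = 0.019, in a range from 0.019 to 0.57). Of 19 YAP/TAZ-TEAD target genes, 9 were higher, 4 lower and 6 not called (10 and 5 adjusted over the list alone), and the list was not called (camera, adjusted p = 0.29, median 0.28).

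CCN2, CCN1 and ANKRD1, classic target genes of YAP and TAZ, were under 3 CPM in both groups. CCN2 was at 0.05 ± 0.01 and 0.41 ± 0.11 CPM (7 and 49 counts, adjusted p = 0.0024), and its call was lost without FAT1 CR replicate 1 (adjusted p = 0.0506, the highest over all alternatives, which began at 1.92e-05). CCN1 did not pass, at 1.76 ± 0.34 and 2.73 ± 0.88 CPM (adjusted p = 0.070), although without parental replicate 1 or FAT1 CR replicate 2, with a block for replicate number, with no filter or with the highest bin it did (adjusted p = 0.0033, 0.036 and 0.0144 for the first 3, with a range from 0.0033 to 0.55 over all alternatives). ANKRD1 fell from 0.60 ± 0.11 to 0.07 ± 0.04 CPM, a log2 fold change of -3.13 that was -3.996 without FAT1 CR replicate 1. AMOTL2, counted together with the pseudogene RPL39P5, rose from 36.9 ± 1.9 to 60.6 ± 1.7 CPM, and NT5E and TGFB2 rose from 0.36 ± 0.10 to 1.86 ± 0.28 and from 0.68 ± 0.10 to 1.74 ± 0.015 CPM. TGFB2 is counted with TGFB2-OT1. In the FAT and Dachsous cadherin list, 2 of 5 tested genes were higher and 2 lower, also when adjusted over the list alone. Beside FAT1 these were FAT4 (0.56 ± 0.12 to 1.54 ± 0.05 CPM), FJX1 (4.70 ± 0.44 to 2.03 ± 0.25 CPM) and DCHS1, whose 4 and 20 counts gave a call that was lost without parental replicate 1, parental replicate 2 or FAT1 CR replicate 2 (adjusted p = 0.082, 0.097 and 0.12) and with DESeq2 (adjusted p = 0.16), in a range that began at 0.0137. The list was not called (camera, adjusted p = 0.29), and its median of 0.16 was positive while its mean of -0.47 and its test pointed down. The mean and the test include FAT1 itself, the targeted gene, at -5.20. The list was not tested without FAT1, so that direction does not describe its other members.

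**Figure D2:**
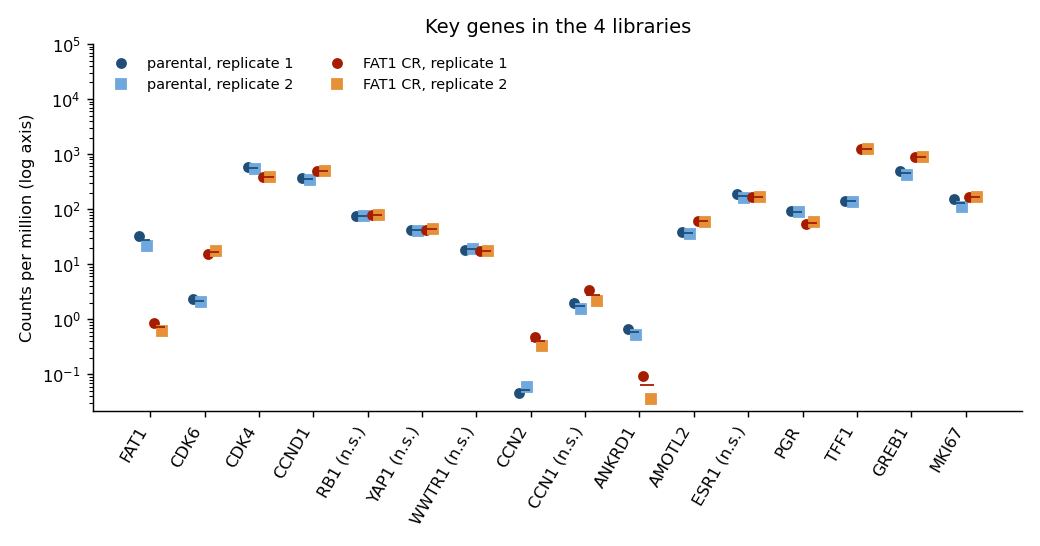
CPM on a log axis (y axis) of the 16 key genes (x axis), with a point for each of the 4 libraries and a line at each group mean. Genes marked n.s. had an adjusted p of at least 0.05 in the edgeR test. CDK6 and TFF1 lay higher and FAT1 lower in both FAT1 CR libraries.

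Most of the listed cell cycle genes were higher, by small amounts. Of 33 mitotic genes, 31 were higher and 1 lower (32 and 1 adjusted over the list alone), with a median log2 fold change of 0.56 (camera, adjusted p = 5.0e-09, and adjusted p = 0.43 with an estimated correlation). DLGAP5, a spindle protein gene, rose from 54.1 ± 0.18 to 134 ± 1.1 CPM, and HMMR, NUSAP1 and CDC25C rose by 1.01, 1.01 and 0.87 on the log2 scale. MKI67, a marker of cycling cells, was at 130 ± 29 and 166 ± 1.1 CPM (log2 fold change 0.35, SE 0.12, adjusted p = 0.045), and its call was lost without FAT1 CR replicate 1 or replicate 2 (adjusted p = 0.161 and 0.16, in a range over all alternatives from 1.25e-11 to 0.161). Of 33 S-phase and E2F target genes, 26 were higher and 1 lower (29 and 1 adjusted over the list alone), with a median of 0.54 (camera, adjusted p = 3.7e-06, and adjusted p = 0.47 with an estimated correlation). RFC4 (33.9 ± 2.8 to 67.0 ± 1.2 CPM), RFC3, POLE2 and SLBP had the largest changes. The RFC4 and POLE2 calls were lost when bins under 200 bases were left out (adjusted p = 0.92 and 0.0501, where all other alternatives gave calls), with RFC4 at a log2 fold change of 0.08 and POLE2 at 1.11 (0.77 with all bins).

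Most replication-dependent histone genes were lower, whereas most genes of the S-phase list were higher, a difference between lists that was not tested. Of 22 tested, 1 was higher and 14 lower (also adjusted over the list alone), with a median log2 fold change of -0.83 (camera, adjusted p = 0.00057, and adjusted p = 0.64 with an estimated correlation). H4C8 fell from 21.7 ± 1.4 to 4.77 ± 0.86 CPM and H2AC6 from 26.0 ± 0.24 to 10.4 ± 0.41 CPM, and H2BC4 and H2BC8 fell by 1.30 and 1.17 on the log2 scale. The genes are near-identical copies, and 20 of the 22 lie on chromosome 6, where the other genes of the same windows were also lower. After the median of those neighbours was subtracted from each gene, the median of the list was -0.45 (-0.46 with histone genes outside the list also left out of the neighbours).

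Estrogen receptor target genes moved in both directions. ESR1 did not pass, at 174 ± 16 and 165 ± 2.0 CPM (adjusted p = 0.44), although without parental replicate 2 it was called lower (log2 fold change -0.17, adjusted p = 0.011, in a range from 0.0109 to 0.85 over all alternatives) and without parental replicate 1 its log2 fold change was 0.02. TFF1, a secreted trefoil factor, rose from 138 ± 5.8 to 1240 ± 15 CPM (3.17, SE 0.06, adjusted p = 2.2e-08) and GREB1 from 453 ± 44 to 882 ± 12 CPM, whereas PGR, the progesterone receptor gene, fell from 90.2 ± 2.2 to 56.8 ± 4.2 CPM (-0.67, SE 0.07). STC2 and TFF3 rose by 2.73 and 2.59 on the log2 scale. SLC7A5, an amino acid transporter gene, fell from 774 ± 99 to 67.0 ± 1.8 CPM. Of 30 listed targets, 14 were higher, 12 lower and 4 not called (14 and 13 adjusted over the list alone), and the list was not called (camera, adjusted p = 0.15, median 0.02), in a range from 0.0845 to 0.842 over the alternatives that ask the same question. The fry test, which asks whether the genes of a list move 1 way on balance without comparing them with other genes, gave an adjusted p of 0.0468.

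Markers of luminal and of basal breast epithelium both included strong rises. Of 16 luminal markers, 9 were higher and 3 lower (also adjusted over the list alone), with a median of 0.36 (camera, adjusted p = 0.00042, and adjusted p = 0.69 with an estimated correlation). AGR2 rose from 159 ± 8.5 to 745 ± 7.9 CPM, and ELF3, counted with an unnamed overlapping gene, from 54.0 ± 0.49 to 121 ± 0.64 CPM, while the androgen receptor gene AR fell from 64.2 ± 14 to 18.1 ± 0.67 CPM. Of 15 basal and myoepithelial markers, 8 were higher and 3 lower (also adjusted over the list alone), with a median of 1.14 (camera, adjusted p = 0.011, and adjusted p = 0.47 with an estimated correlation). CAV1, the caveolin gene, rose from 2.28 ± 0.60 to 32.2 ± 1.3 CPM and EGFR from 0.32 ± 0.15 to 2.59 ± 0.34 CPM. KRT6A was at 0.08 ± 0.01 and 0.89 ± 0.06 CPM, and TP63, the transcription factor of basal cells, fell from 2.33 ± 0.08 to 0.21 ± 0.19 CPM. The log2 fold change of TP63, -3.51, was -2.78 without FAT1 CR replicate 1 and -4.87 without FAT1 CR replicate 2.

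Most type I interferon response genes fell. Of 35 tested type I interferon response genes, 32 were lower and 1 higher (also adjusted over the list alone), with a median log2 fold change of -2.99 (camera, adjusted p = 3.2e-51, and adjusted p = 0.43 with an estimated correlation). The median was also -2.99 with members at 3 or fewer counts set to the floor of 3. IFI44 had 2399 counts in parental and 3 in FAT1 CR libraries, a ratio of 713 (95% interval 244 to 3460), and IFI44L was at 8.42 ± 0.68 and 0.04 ± 0.05 CPM. XAF1 fell from 11.8 ± 2.7 to 0.14 ± 0.06 CPM and IFIT1, an RNA-binding antiviral protein gene, from 33.3 ± 5.6 to 0.53 ± 0.11 CPM. Of 17 antigen presentation genes, 12 were lower and 2 higher (13 and 2 adjusted over the list alone), with a median of -0.92 (camera, adjusted p = 0.00024, and adjusted p = 0.69 with an estimated correlation). PSMB8, an immunoproteasome subunit gene, fell from 1.88 ± 0.40 to 0.06 ± 0.07 CPM and NLRC5, a regulator of class I genes, from 2.58 ± 0.06 to 0.59 ± 0.37 CPM. TAP2, counted with HLA-DOB and another overlapping gene, fell from 30.3 ± 3.0 to 5.97 ± 0.40 CPM, and HLA-DRB1, counted with HLA-DRB6, rose from 2.02 ± 0.81 to 7.41 ± 0.31 CPM. Without FAT1 CR replicates 1 and 2 the log2 fold change was -4.10 and -6.74 for PSMB8 (-4.94 with both), -6.85 and -12.12 for IFI44L (-7.89 with both) and -8.34 and -13.21 for IFI44 (-9.36 with both), and that of NLRC5 (-2.11) was -3.00 without FAT1 CR replicate 1. Of these 17 genes, 12 lie on chromosome 6, and after the median of window neighbours was subtracted the list's median was -0.77.

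NF-kB and inflammatory genes were not called as a list (3 higher and 5 lower of 13, also adjusted over the list alone, camera, adjusted p = 0.64). Its median of -0.22 and its test pointed down and its mean was 0.02. LIF (0.34 ± 0.26 to 1.36 ± 0.12 CPM), TNFAIP3, RELB and TRAF1 were called at low levels. The LIF call was lost without FAT1 CR replicate 2 (adjusted p = 0.066), the TNFAIP3 and RELB calls without FAT1 CR replicate 1 (adjusted p = 0.071 and 0.089), and the TRAF1 call without any 1 of the 4 libraries (adjusted p = 0.0624 to 0.248), with each other scaling, with DESeq2 and with longer bins. Over all alternatives their adjusted p began at 2.81e-09 for LIF, 1.1e-05 for TNFAIP3, 5.71e-05 for RELB and 0.0336 for TRAF1. The log2 fold change of LIF, 1.98, was 1.36 without parental replicate 1 and 3.12 without parental replicate 2.

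**Figure D3:**
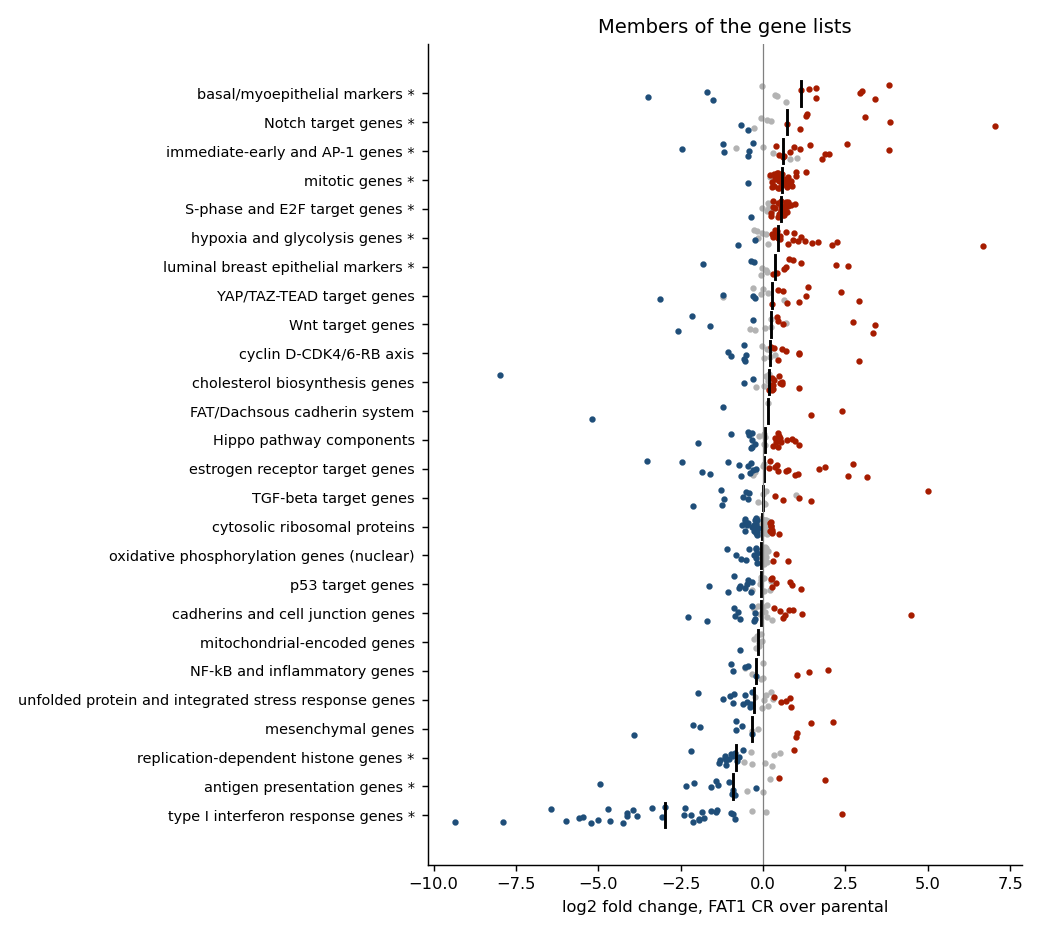
Log2 fold change of FAT1 CR over parental (x axis) of each tested member of the 26 lists (y axis), with a point per gene and a black bar at the list median. Red and blue points are genes called higher and lower, grey points were not called, and asterisks mark lists called by camera. The interferon list lies lowest, with a median of -2.99.

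Hypoxia and glycolysis genes and genes of the Notch list were higher as lists. Of 29 hypoxia and glycolysis genes, 21 were higher and 2 lower (also adjusted over the list alone), with a median of 0.45, the same with CA9 at the floor of 3 counts (camera, adjusted p = 3.7e-06, and adjusted p = 0.65 with an estimated correlation). NDRG1 rose from 32.7 ± 3.8 to 105 ± 5.6 CPM and EGLN3, an oxygen-sensing hydroxylase gene, from 4.34 ± 0.45 to 20.4 ± 0.84 CPM. CA9 had 1 and 115 counts, a ratio of 129 (95% interval 22.7 to 5140) with a log2 fold change of 6.67 that was 8.91 without parental replicate 1 and 5.79 without parental replicate 2, and ADM was at 0.15 ± 0.02 and 0.64 ± 0.06 CPM. Of 13 genes of the Notch target list, 7 were higher and 2 lower (also adjusted over the list alone), with a median of 0.72 (camera, adjusted p = 0.00024, and adjusted p = 0.43 with an estimated correlation). The effector gene HEY2 rose from 0.13 ± 0.12 to 18.1 ± 1.1 CPM, the ligand gene DLL1 from 2.02 ± 0.36 to 17.1 ± 0.24 CPM and LFNG from 24.7 ± 2.0 to 61.9 ± 2.0 CPM, and DTX1 was at 0.07 ± 0.03 and 0.99 ± 0.05 CPM. After the median of window neighbours was subtracted, the median of the Notch list was 0.33. The log2 fold change of HEY2, 7.05, was 6.35 without parental replicate 1 and 8.55 without parental replicate 2.

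Of 24 immediate-early and AP-1 genes, 13 were higher and 6 lower (13 and 7 adjusted over the list alone), with a median of 0.62 (camera, adjusted p = 0.030, and adjusted p = 0.65 with an estimated correlation). That call was lost without parental replicate 2 (adjusted p = 0.079) and with camera on limma-voom values (adjusted p = 0.055), in a range from 0.00881 to 0.65. DUSP4 rose from 2.21 ± 0.02 to 31.4 ± 0.74 CPM and EGR1 from 1.55 ± 0.28 to 6.26 ± 0.39 CPM, while DUSP5 fell from 14.6 ± 0.42 to 2.66 ± 0.24 CPM. DUSP4 and DUSP5 encode phosphatases of MAP kinases. ETV5, counted with DGKG, lost its call without either FAT1 CR library (adjusted p = 0.116 and 0.087 without replicates 1 and 2) and with DESeq2 (adjusted p = 0.218), in a range that began at 7.6e-11. Its log2 fold change of 2.54 was 6.06 without parental replicate 1 and 1.57 without parental replicate 2.

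Other lists were not called. Of 13 mesenchymal genes, 4 were higher and 7 lower (median -0.34, camera, adjusted p = 0.15, in a range from 0.098 to 0.65, and 0.0202 with fry, which does not compare the list with other genes), with falls in COL5A1 (148 ± 5.4 to 39.5 ± 0.29 CPM), SERPINE1 and CDH2, the N-cadherin gene, and a rise in LOX from 0.20 ± 0.11 to 0.89 ± 0.05 CPM. The log2 fold change of CDH2, -3.93, was -2.88 without FAT1 CR replicate 1 and -8.73 without FAT1 CR replicate 2, and that of LOX, 2.13, was 2.83 without parental replicate 2. Of 26 cadherin and cell junction genes, 8 were higher and 10 lower (camera, adjusted p = 0.67). Its median of -0.06 and its test pointed down, its mean was 0.05, and the direction of the test turned without parental replicate 1 (adjusted p = 0.61, in a range from 0.501 to 0.983). PKP1, a desmosome gene, rose from 4.19 ± 1.8 to 93.3 ± 1.6 CPM and the tight junction gene TJP1 from 51.4 ± 2.5 to 117 ± 1.7 CPM, while DSC2 and CDH3 fell by 2.28 and 1.71 on the log2 scale. Of 25 p53 target genes, 7 were higher and 10 lower (median -0.05, camera, adjusted p = 0.47), among them TP53I3, PLK2 and CDKN1A lower and GDF15 higher. For these 3 lists the counts adjusted over the list alone were equal to those over all genes.

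Of 19 TGF-beta targets, 5 were higher and 8 lower (camera, adjusted p = 0.46). Their median of 0.01 and mean of 0.09 were above 0 while the test pointed down, and with COL4A2 at the floor of 3 counts the median was also 0.01. TGFBI rose from 18.6 ± 2.1 to 50.5 ± 3.0 CPM and BHLHE40 fell from 30.1 ± 1.3 to 12.5 ± 0.06 CPM, and COL4A2 had 1 and 36 counts, a ratio of 40.4 (95% interval 6.8 to 1640). The log2 fold change of COL4A2 was 4.18 without parental replicate 1 and 7.21 without parental replicate 2. Of 16 Wnt targets, 6 were higher and 4 lower (camera, adjusted p = 0.64), with a median of 0.24 and a mean of 0.31 where the test pointed down, a direction that turned with no filter and on limma-voom values (adjusted p = 0.781 and 0.655, in a range from 0.405 to 0.924). LGR6, LEF1 and APCDD1 were higher and TCF7 lower, all at mean levels under 5 CPM. Without parental replicates 1 and 2 the log2 fold change was 4.78 and 2.61 for LEF1 (3.35 with both) and 4.12 and 2.03 for APCDD1 (2.74 with both), and that of LGR6 (3.41) was 4.21 without parental replicate 2. Of 24 cholesterol biosynthesis genes, 12 were higher and 3 lower (camera, adjusted p = 0.16), with a positive median (0.19) and test and a negative mean (-0.12). With PCSK9 at the floor of 3 counts the median was also 0.19 and the mean was 0.04. MVK rose from 19.9 ± 3.1 to 42.5 ± 2.0 CPM, SQLE and MSMO1 rose by 0.59 and 0.57 on the log2 scale, and PCSK9 had 66 and 0 counts, at least 19.6-fold lower. The cholesterol list was called without parental replicate 1 (adjusted p = 0.038), with no filter (0.0121) and with camera on limma-voom values (0.0165), in a range up to 0.855. Counts adjusted over the list alone were again equal for these 3 lists.

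Of 24 unfolded protein and stress response genes, 5 were higher and 12 lower (median -0.28, camera, adjusted p = 0.25), among them SLC3A2 (715 ± 43 to 181 ± 5.8 CPM), DDIT3, PHGDH and HERPUD1, all lower. Of 39 nuclear genes of oxidative phosphorylation, 3 were higher and 11 lower (3 and 10 adjusted over the list alone, median -0.05, camera, adjusted p = 0.39), with ATP5F1B and UQCRC1 (221 ± 16 to 125 ± 5.7 CPM) lower. NDUFB10 was lower (119 ± 1.5 to 75.2 ± 0.31 CPM), but its log2 fold change turned to 0.09 with bins of at least 200 bases (adjusted p = 0.917, in a range that began at 1.07e-15), and NDUFA9, higher by 0.75, is counted with several overlapping genes. Of 61 cytosolic ribosomal protein genes, 9 were higher and 18 lower (median -0.03, camera, adjusted p = 0.51), with RPLP1, RPS18, RPS24 and RPL14 falling by 0.64, 0.56, 0.55 and 0.54 on the log2 scale. Of 8 mitochondrial-encoded genes, MT-ND1 alone was called (581 ± 164 and 354 ± 6.5 CPM, adjusted p = 0.0049), and that call was lost without FAT1 CR replicate 1 (adjusted p = 0.0572, in a range that began at 1.9e-27). The mitochondrial share of counts was 1.80% and 2.74% in parental replicates 1 and 2 and 1.94% and 2.05% in FAT1 CR replicates 1 and 2. The mitochondrial list was not called (camera, adjusted p = 0.60, median -0.16), but it was called lower without parental replicate 1 (adjusted p = 0.00036) and its direction turned without parental replicate 2 (adjusted p = 0.58), in a range from 0.000358 to 0.867. Counts adjusted over the list alone were equal for the stress, ribosomal and mitochondrial lists.

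Markers of cell types that an MCF-7 culture should lack were few. Of 12 fibroblast markers 4 were tested, with COL6A3 (0.57 ± 0.10 to 5.86 ± 0.32 CPM) and FBLN1 higher and COL1A1 lower (33.6 ± 3.8 to 19.1 ± 1.3 CPM). Of 14 leukocyte markers 4 were tested, with CSF1R lower (1.05 ± 0.42 to 0.12 ± 0.06 CPM), and of 11 endothelial markers 4 were tested, with VWF and ESAM higher at mean levels of 0.77 and 1.78 CPM in FAT1 CR cells. The VWF call was lost without either FAT1 CR library (adjusted p = 0.106 and 0.058 without replicates 1 and 2) and the ESAM call without FAT1 CR replicate 1 (adjusted p = 0.0756), in ranges that began at 7.69e-05 and 1.27e-05. Without parental replicate 1 the log2 fold change of VWF was 2.39 instead of 1.68, and without FAT1 CR replicate 2 that of CSF1R was -3.72 instead of -3.13. With the highest bin of each gene the COL1A1 and FBLN1 calls were lost (adjusted p = 0.0908 and 0.0847, where all other alternatives gave calls). None of 11 erythroid and liver markers passed the filter. These lists had under 5 tested members each and were not tested as lists.

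Neighbouring genes moved together along the chromosomes. The median log2 fold change was 0.33 over 604 genes of chromosome 14, 0.21 over 982 genes of chromosome 12, -0.31 over 201 genes of chromosome 21 and -0.19 over 908 genes of chromosome 6, and 12 of 23 chromosomes lay at least 0.1 from the median of all genes. Among 359 windows of neighbouring genes, the SD of the window medians was 0.27, against 0.05 between the parental libraries and 0.03 between the FAT1 CR libraries. There were 42 windows at 0.3 or above and 38 at -0.3 or below. The highest median was 1.08, at 102.0 to 108.6 Mb of chromosome 12, where 39 of 50 genes were higher and 2 lower. The next was 0.80, at 28.8 to 30.2 Mb of chromosome 16, which holds ALDOA. The lowest medians were on chromosome 12, with -0.98 at 34.2 to 48.0 Mb and -0.86 at 57.1 to 64.2 Mb, the former holding SLC38A1 and SLC38A2 and the latter CDK4, and on chromosome 6, with -0.84 at 0.3 to 10.4 Mb.

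**Figure D4:**
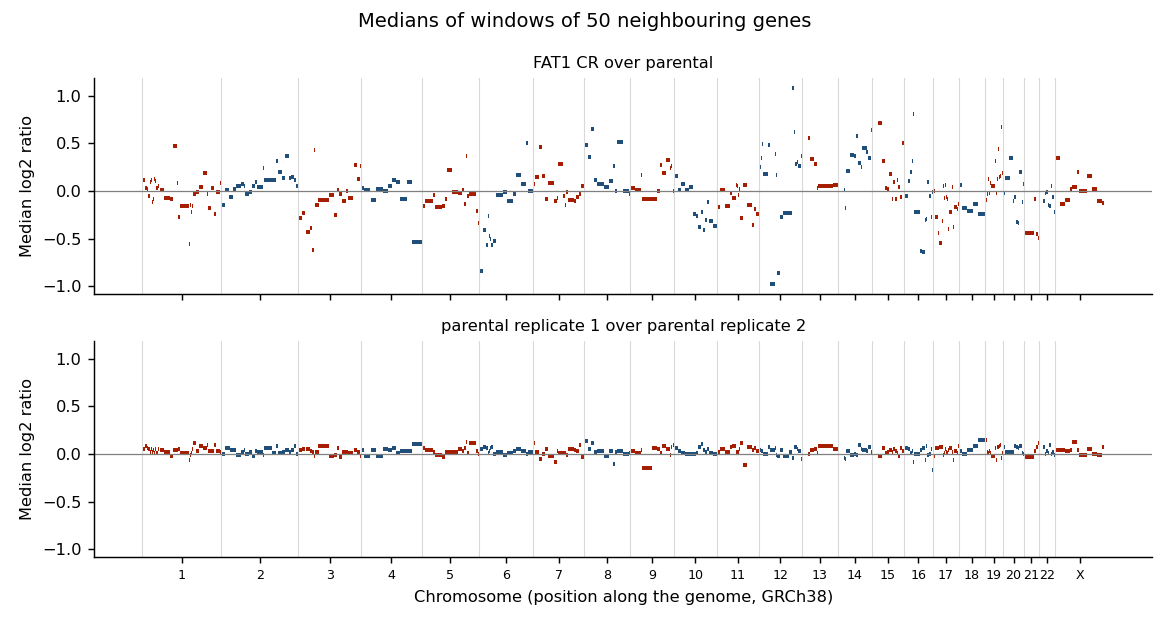
Median log2 ratio (y axis) of windows of neighbouring genes along the genome (x axis, chromosomes 1 to 22 and X, colours alternating by chromosome). The upper panel shows FAT1 CR over parental, where medians range from -0.98 to 1.08, and the lower panel shows the 2 parental libraries against each other, where they stay within 0.24 of 0.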

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

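The alternatives using the highest bin, bins of at least 200 bases or no joint entries were chosen after seeing the data. Genes called in both settings had the same direction except under the first pair of these, with 6909 shared calls (6900 in the same direction) for the highest bin and 6858 (6850) for the longer bins. Changed genes numbered 7448 to 9470 over scalings, filters, tests and bins, and 6202 at an adjusted p under 0.01. DESeq2 called 7695 genes and kept 87.9% of the calls. A test against a log2 fold change of 1 (glmTreat) called 1668 genes, by its construction, and the stricter filter left 1997 genes changed by at least 1, since fewer were tested. Leaving out 1 library gave 5661 to 9775 changed genes, 2631 to 4769 higher and 2980 to 5040 lower, 2467 to 3264 changed by at least 1, a FAT1 log2 fold change of -5.47 to -4.87, 9 to 12 lists, 81 to 86 shifted windows and a median of -1.03 to -0.86 near FAT1, with fewer libraries in 1 group. The median near FAT1 was -0.80 within 2 Mb, -0.92 within 10 Mb, -0.93 by library size only and -0.92 with the stricter filter. With an estimated correlation camera called 0 of 26 lists (3 at an unadjusted p under 0.05), while fry, which tests another hypothesis, called 12 in 1 direction. Most called lists had estimated correlations above the preset 0.01, from 0.047 for mitotic genes to 0.44 for interferon genes and 0.51 for antigen presentation genes. The p-values of those lists at the preset correlation may therefore be too small. The Notch list (estimated correlation -0.054) and the basal list (-0.015) also lost their calls, although both estimates lay below the preset 0.01. A higher correlation was thus not the only source of the lost calls. With 2 libraries per group that form of the test could call few lists. The cause of the other differences between alternatives was not tested.

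The log2 fold change of ESR1 was above 0 without parental replicate 1 (0.0205, and from -0.171 to 0.0205 without any 1 library), with the highest bin (0.0662) and with longer bins (0.0328), and that of NDUFB10 with longer bins (0.0862). The direction of camera turned for the Wnt list with no filter (adjusted p = 0.781) and on limma-voom values (0.655), for the cadherin and junction list without parental replicate 1 (0.613, and 0.613 to 0.913 without any 1 library), with the highest bin (0.501) and with longer bins (0.713), and for the mitochondrial list without parental replicate 2 (0.581, and 0.000358 to 0.644 without any 1 library). The cause was not tested. Of the other values of named genes, 1983 were the same in direction and call, 30 lost the call and 7 gained it, and for lists these numbers were 388, 12 and 6.

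The labels do not say that equal replicate numbers mark a shared day, and the differences between replicates 1 and 2 had a correlation of 0.0989 across genes between the groups. A block for replicate number gave 9677 changed genes. At 3 counts, the smallest level counted as seen was 0.044 to 0.055 CPM by library.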

Other observations

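The gene families that follow were chosen after their values were seen, and no enrichment was tested. Of 8 tested kallikrein-related peptidase genes, secreted serine proteases that lie together at 50958631 to 51084245 on chromosome 19, 7 were higher in FAT1 CR cells and 0 lower, under each of the 4 scalings (edgeR). KLK6 rose from 0.48 ± 0.23 to 14.4 ± 0.56 CPM and KLK10 from 0.04 ± 0.01 to 2.90 ± 0.02 CPM (SD, n = 2 each). KLK7, KLK13 and KLK12 had 0 counts in parental libraries and were at least 22.4-fold, 16.8-fold and 15.7-fold higher, against a floor of 3 counts over the group. These 3 genes passed the filter only through their FAT1 CR counts, and genes of the family that did not pass it were not counted. The scalings moved the median of the 8 genes only between 7.54 and 7.57, so they could hardly change the calls. KLK14 had 36 and 39 counts and was not called. Of 5 mucin genes, MUC5AC and MUC5B were higher under each scaling, MUC5B from 3.10 ± 0.36 to 152 ± 6.8 CPM, and the other 3 did not pass. All 3 tested Schlafen genes were higher, SLFN5 from 2.42 ± 0.11 to 18.8 ± 0.33 CPM. Of 20 amino acid transporter genes, 6 were higher and 9 lower (7 and 9 with upper quartile factors), among them SLC1A1, which rose from 0.16 ± 0.01 to 2.11 ± 0.39 CPM, and SLC1A4, which fell from 8.92 ± 0.19 to 3.65 ± 0.55 CPM. Of 15 serpin genes 3 were higher and 8 lower, of 12 ADAMTS protease genes 3 and 5, of 11 S100 genes 3 and 4 (3 and 3 with upper quartile factors or library size only) and of 3 APOBEC3 genes 2 and 0. SLC7A5 and SLC3A2 of the transporters are also members of the estrogen receptor and stress response lists.

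The balance of counts between the 5′ and 3′ parts of genes differed between groups in 314 of 11050 genes (limma), and by at least 2 on the log2 scale in 13 genes with an entry of their own. In LMCD1, the 5′ part had 1600 and 1488 counts in parental libraries and 128 and 113 in FAT1 CR libraries, while the 3′ part had 44 and 42 against 96 and 70 (difference in the log2 ratio of 5′ to 3′ counts -4.40, adjusted p = 3.0e-06). In TACC2, the 5′ part had 614 and 452 counts against 8 and 18, and the 3′ part 3172 and 3303 against 1668 and 1438 (difference -3.64, adjusted p = 0.00048).

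For the patterns that follow, the tests by shuffled gene order, by blocks of neighbouring genes and by FAT1 against its neighbours were chosen after the results were seen. Neighbouring genes moved together along the chromosomes, with an SD of window medians of 0.265. In 1000 shuffles of gene order the SD reached at most 0.101, and after a trend on GC content and exonic length was removed it was 0.262 (0.266 before), which argues against scatter of single genes and against that bias as the whole source. Copy number differences between the cultures are a candidate explanation: over 359 windows, the medians of the lower and the higher expressed genes had a Pearson r of 0.654 (Spearman rho 0.608, permutation p = 1e-05, the smallest that 100000 permutations can give, and r = 0.638 without the 2 windows farthest from the median). Any other mechanism acting on regions would give such a relation too, windows are not independent samples, and DNA was not measured. Of 3098 genes changed by at least 1, 85.2% kept such a change after the median of their window was subtracted.

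Type I interferon response genes were lower in FAT1 CR cells, with a median of -2.99. After the trend on GC content and length was removed the median was -2.95, which argues against that bias as the whole source. After each gene's window median was subtracted it was -2.72, with fallen members on 14 chromosomes. No window median lay below -0.98, so the subtraction could not have removed a fall of this size. The values show only that shifts shared by whole windows were too small to be the whole source. Copy number changes of single members, which medians of 50 genes do not show, were not tested. Effects on these genes of copy number elsewhere in the genome were not tested. The labels name 1 edited derivative, so FAT1 loss cannot be told apart from other differences that arose in that derivative or in the parental culture, and this holds for every comparison of the groups.

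Genes within 5 Mb of FAT1 were lower, with a median of -0.96. The median was -0.989 after the trend on GC content and length was removed, which argues against that bias. Of 17336 blocks of as many neighbouring genes elsewhere 41 had a median as low, in 4 separate regions, so a regional shift like others along the genome stays open. FAT1 itself lay at -4.24 relative to its neighbours' median (their median absolute deviation was 0.546). The 14 genes within 2 Mb had a median of -0.80 and a lowest value of -3.00, against -5.20 for FAT1. These values argue against a loss shared evenly by FAT1 and those 14 genes as the whole source of FAT1's fall. All 14 lie at lower positions than FAT1. On its other side the nearest tested gene, ENSG00000278974, starts at 188740507 and was at 0.23 CPM in parental cells. A loss of FAT1 together with the stretch before that gene would not be seen in these values. Beyond 2 Mb, TENM3 fell by 4.13 on the log2 scale and TENM3-AS1 at least 99.2-fold against 36.7-fold for FAT1. Whether a loss that differed along the region accounts for FAT1's own fall stays open. A loss of DNA copies around FAT1 in part of the chromosomes, or an effect of editing on the region, may underlie the neighbours' fall, and these data do not part the explanations.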
